A study of Hebeloma cylindrosporum with 12 samples.

How the data were processed

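RNA was sequenced from mycelium of Hebeloma cylindrosporum in 12 libraries, 3 for each combination of treatment (root contact or control) and time (2 or 4 days). Per the labels' protocols, seedling roots were dipped in a mycelial homogenate, mycelium was scraped from 40 roots per collection, and control mycelium was grown from the same homogenate without a plant. The labels call the 3 libraries of a group biological replicates. The series design text gives a read length of 150 bases. Samples were grouped by their titles.

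Per the file headers, each deposited file holds 2 read counts for every gene model of the JGI Hebcy2 genome: unique gene reads and total gene reads. The authors also deposited an RPKM value per gene model, per the file headers. The mapper, the counting tool, their versions and their filters are not given in the sources used here. The RPKM values were checked against the counts. In all 165883 pairs of gene and library with a read, total reads, RPKM and the sum of total reads gave the same whole gene model length to within 0.01 nt. The RPKM is thus computed from total reads over a fixed length, with a median of 1145 nt. Only 55.4% of the lengths are multiples of 3, so they are called gene model lengths. Every row named a gene ID. Total gene reads were used as the counts, and unique reads, which made up 99.1% to 99.3% of them, as an alternative. For 629 genes less than 90% of the reads were unique, and their levels are uncertain where near-identical models share reads.

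Libraries held 21.8 to 73.9 M total gene reads. A gene with 0 reads in a library allows up to 3 reads, or 0.0406 to 0.137 CPM. Such floors and intervals (95%, exact binomial) cover counting error only, because reads without molecular identifiers are not independent molecules. Within a group, each pair of libraries differed by far more than sampling noise (chi-square of 27.5 to 564 per gene), so no library is a copy of another's reads. This does not show whether the libraries were prepared from separate mycelia. They were treated as biological replicates because the labels call them so.

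Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, two-sided). One model held all 12 libraries with 4 group means. TMM scaling and the default filterByExpr filter left 13411 genes, and p-values were adjusted by the Benjamini-Hochberg method over these genes in each of the 5 comparisons. A gene was called at an adjusted p under 0.05. The comparisons were root contact against control at 2 and at 4 days, 4 against 2 days in each treatment, and the interaction, which is the contact effect at 4 days minus that at 2 days. Levels are total gene reads as CPM, scaled by TMM and given as mean ± SD. Standard errors of log2 changes were derived from the F statistic. Where all libraries of a control group had 0 reads, a fold is given as a lower bound against 3 reads over the group, because the fitted fold then depends on the prior count. Principal components used log2 CPM with a prior count of 2. Overlaps were tested with a one-sided Fisher's exact test.

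The groups, comparisons, tests, first set of alternatives, gene lists and the rule for named genes were chosen before the data were examined. Because the files do not pair IDs with functions, the fallback of that rule applied: the 2 largest log2 changes each way per comparison, among genes with adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups (for the interaction, between the contact differences of the days). Complete separation of 3 against 3 libraries has a chance of 10% without any effect. The ranking used fitted changes, so genes with 0 control reads could be picked before genes with a measured increase. At 2 days gene 434858 (at least 565-fold) ranked above gene 32057 (5741-fold, interval 1589 to 47410). At 4 days gene 33057 (at least 7352-fold) ranked above gene 410766 (88250-fold, interval 15840 to 3486000). The 32 gene lists set up by keyword (transporters, secreted proteins, cell wall enzymes and others) could not be matched, as the IDs came without functions. No list was tested.

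The replicate numbers 1 to 3 recur in every group, and no label says what a number marks. Deviations from the group means of log2 CPM were compared between equally numbered libraries of the groups in each comparison. All 12 correlations were above the limit of 0.1 set for a pairing (0.163 to 0.664). For replicate 1 these correlations were 0.43 to 0.664. Its highest correlation with a different number in the same comparison was between -0.563 and -0.217, so the pairing is clearest there. Deviations in a group sum to 0, so the negative values follow in part from the positive ones, and the 12 correlations are not independent. For replicates 2 and 3 the highest correlation with a different number reached 0.346. In the contact comparison at 2 days it came close to the correlation of equal numbers (0.214 against 0.269 and 0.345 against 0.381). In other comparisons replicate 3 correlated as highly as replicate 1, at 0.43 for both in contact at 4 days and at 0.658 and 0.657 for time on roots. The pairing thus comes from the data and is less certain for replicates 2 and 3, above all in the contact comparison at 2 days. A fit with the replicate number as a block lowered the common dispersion from 0.0847 to 0.0401. Its counts stand beside the results.

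The procedure was tested on simulated data with the means, depths and dispersions of the 13411 genes and 200 genes changed by known folds in the 2-day contact group. In the contact comparison at 2 days, 2% of genes changed 1.5-fold were recovered, 24% at 2-fold, 82% at 4-fold and 98% at 8-fold, and 10 unchanged genes were called. In the interaction, the shares were 0%, 0%, 50% and 84%, and 1 unchanged gene was called. Each gene had 1 mean over all groups before the changes, and changed genes were drawn from those at 1 CPM or more. No replicate structure was simulated. Fewer genes were called than in the real comparisons, which makes the adjusted cutoff stricter. The shares therefore belong to this setting and are not the sensitivity of the real comparisons.

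Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scaling factors, no filter or a filter of 10 CPM in 3 libraries, fold thresholds, fits of only the 6 libraries compared, the replicate block and each library left out in turn. Added after the data were seen were unique reads, thinning of every library to the 21.8 M reads of the shallowest, removal of the trend on gene model length, and leaving out the 4 replicate 1 libraries. DESeq2 gave no adjusted p to 294 genes for time in controls and to 569 in each other comparison, and these were left out. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.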

Results

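Transcript abundance was measured by RNA sequencing in the mycelium of Hebeloma cylindrosporum, a basidiomycete that forms ectomycorrhizas with pine. Mycelium scraped from the root surface of Pinus pinaster seedlings (root contact) was compared with mycelium grown on the same medium without a plant (control). Both were collected after 2 and after 4 days, which gave 4 groups of 3 libraries. The comparisons address how the fungal transcriptome differs in the presence of the root before symbiotic structures form, and whether that difference changes between the days. Read counts were available for 15382 gene models, of which 1147 had no read in any library and 13140 had a read in every library. After a filter on low counts, 13411 genes were tested. Genes are given by their JGI Hebcy2 protein ID, because the files do not pair the IDs with names or functions.

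Control libraries held 23.8, 21.8 and 23.3 M gene reads at 2 days and 25.0, 40.3 and 33.1 M at 4 days, in the order of their replicate numbers. Root contact libraries held 61.9, 73.9 and 69.4 M at 2 days and 60.2, 73.1 and 70.3 M at 4 days. Depth was therefore 2.44 times higher, on average, with root contact than in the controls, and it moved with the contact comparison at both times. The 10 most abundant genes took between 9.11% and 14.2% of the reads of a library. In each of the 4 groups this share was highest in replicate 1, and the gene model behind an average read was shortest there. That length was 1250.5 nt in replicate 1 of the 2-day controls against 1562 and 1516 nt in the others, and 1312 nt in replicate 1 of the 4-day contact libraries against 1408 and 1466 nt.

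The first principal component of the 500 most variable genes carried 70.98% of the variance and separated root contact from control. All 6 control libraries had scores between -44.4 and -34.1, and all 6 contact libraries had scores between 11.4 and 65.2. Contact libraries of 4 days lay farther along it (51.2 to 65.2) than those of 2 days (11.4 to 33.8). The second component carried 13.4% and separated 2 from 4 days within each treatment. With all 13411 tested genes it carried 22.6% and did not separate the days. Replicate 1 then lay lowest among the 2-day libraries of each treatment (-98.9 in controls and -49.4 with contact, the others between -3.13 and 0.448), and replicate 1 of 4 days lay among the other 2-day libraries (-1.21 and -0.80). Spearman correlations of log2 CPM were 0.922 to 0.995 between libraries of one group and 0.893 to 0.966 between treatments on the same day. Between the days within a treatment they spanned a similar range, 0.887 to 0.971.

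**Figure D1:**
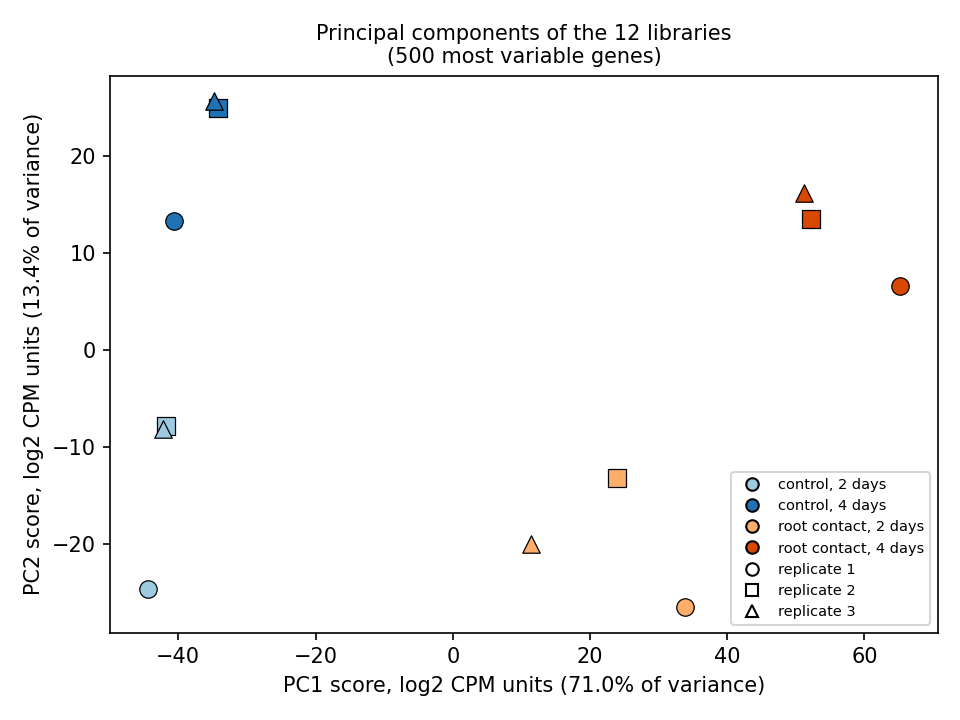
Scores of the 12 libraries on the first and second principal components of log2 CPM (500 most variable genes), coloured by group, with the replicate number as the symbol. Control libraries lie below -34 on the first component and root contact libraries above 11, and the second component of these 500 genes, but not that of all tested genes, separates the days.

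After 2 days of root contact, 1462 genes were higher and 1074 were lower than in control mycelium of the same age (edgeR quasi-likelihood test, adjusted p under 0.05). Large differences were almost all increases. Of the genes called, 171 were at least 8-fold higher and 9 at least 8-fold lower, and 68 were at least 32-fold higher while 0 were 32-fold lower. Among genes called lower, the median log2 change was -1.05, and among genes called higher it was 1.35. Changes from 2 to 4 days were skewed likewise, so the skew is not particular to contact. In controls 63 genes were at least 8-fold higher and 7 lower, and on roots 79 and 9.

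The largest increase at 2 days by the fixed rule was that of gene 32027, which had 0 reads in all 6 control libraries. With root contact it reached 138.5 ± 136.6 CPM (SD, n = 3) at 2 days, with 289, 103 and 22.9 CPM in the libraries. Against a floor of 3 reads over the 3 control libraries this was at least 3076-fold higher (adjusted p = 0.00176). That bound was 1565-fold without contact replicate 1, 4661-fold without contact replicate 3, and 2019- and 1993-fold without control replicates 2 and 3, because fewer control reads raise the floor. Gene 434858 also had 0 reads in the 2-day controls and reached 27.4 ± 41.0 CPM, which was at least 565-fold higher (adjusted p = 0.00862). Most of that level came from 1 library, with 74.8 CPM in replicate 1 against 4.38 and 3.07 CPM in the others. Its bound was 94.4-fold without that library, 875-fold without contact replicate 3, and 371- and 366-fold without control replicates 2 and 3. The largest decrease by the same rule was that of gene 68284, from 60.9 ± 20.1 CPM in controls to 6.996 ± 3.56 CPM (8.72-fold lower, log2 change -3.12 ± 0.43 SE, adjusted p = 0.000736). Gene 428494 was 5.01-fold lower (23.2 ± 10.1 against 4.63 ± 0.959 CPM, adjusted p = 0.00219). It was not called at 4 days, when it stood at 13.6 ± 4.33 CPM in controls and 10.3 ± 3.15 CPM with contact (adjusted p = 0.44). Its interaction was not called (edgeR quasi-likelihood test, adjusted p = 0.106), although it was with the replicate number as a block (adjusted p = 0.00628).

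Deviations from the group means correlated between equally numbered libraries, with the widest gap to other numbers for replicate 1. With the replicate number as a block, the counts at 2 days were 2433 higher and 2132 lower, and the 2536 genes called without the block all kept their call. The balance of higher and lower genes depended on the scaling: 57.7% of the calls were higher with TMM factors, 32.7% with upper-quartile factors and 18.8% with library size alone. The median log2 change of all genes was -0.25 under upper-quartile factors and -0.44 under library size alone. A fit of only the 6 libraries compared called 624 genes higher and 183 lower. Genes called lower numbered 588 without contact replicate 1 and 491 without contact replicate 2.

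After 4 days of root contact, 1900 genes were higher and 1998 lower than in controls of that age, or 29.1% of the genes tested against 18.9% at 2 days. Genes called higher again held the large differences: 233 were at least 8-fold higher and 19 at least 8-fold lower, and 98 were at least 32-fold higher while 0 were 32-fold lower. Gene 32027 stood at 1120 ± 525 CPM with contact, again with 0 reads in the 3 controls, which was at least 41700-fold higher (adjusted p = 0.000571). Gene 33057, with a model of 288 nt, likewise had 0 reads in controls and reached 199 ± 90.7 CPM, at least 7352-fold higher (adjusted p = 0.00064). Without 4-day control replicates 2 and 3 in turn, these bounds were 24320- and 27220-fold for gene 32027 and 4288- and 4800-fold for gene 33057. It stood at 10.7 ± 9.12 CPM after 2 days of contact.

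Among the decreases at 4 days, gene 444745 was 5.69-fold lower with contact (98.7 ± 32.8 against 17.3 ± 2.20 CPM, log2 change -2.51 ± 0.28 SE, adjusted p = 0.000156). At 2 days the same gene stood at 68.2 ± 15.5 CPM in controls and 65.5 ± 13.1 CPM with contact (adjusted p = 0.902). Gene 24837 was 5.68-fold lower at 4 days (89.5 ± 37.3 against 15.8 ± 2.29 CPM, adjusted p = 0.00101). Only 80.6% of its reads mapped to it alone, so its level is uncertain where near-identical models share reads.

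At 4 days the fit with the replicate block called 3026 genes higher and 3003 lower, and 3897 of the 3898 calls without the block were kept. Of the calls, 48.7% were higher with TMM factors, 27.7% with upper-quartile factors and 23.3% with library size alone. The median log2 change of all genes was -0.28 under upper-quartile factors and -0.40 under library size alone. A fit of only the 6 libraries compared called 2636 genes higher and 2562 lower, whereas at 2 days such a fit called fewer than the main fit. The size of the gap in calls between the days thus depended on which libraries were fitted together. The counts fell to 1205 higher and 1241 lower without control replicate 3, to 1191 and 1063 without contact replicate 1, and to 1230 lower without contact replicate 2.

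**Figure D2:**
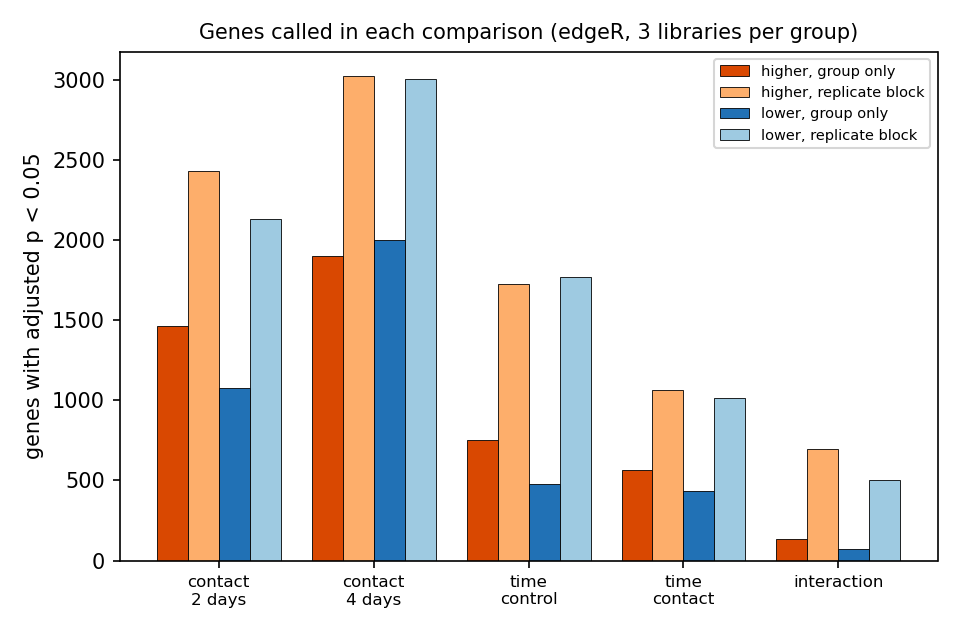
Number of genes with adjusted p under 0.05 in each of the 5 comparisons, counted from 0, split into higher and lower and shown for the fit with groups only and for the fit with the replicate number as a block. Contact at 4 days gave the most calls (1900 higher and 1998 lower, or 3026 and 3003 with the block) and the interaction the fewest (137 and 69, or 693 and 505).

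Many genes responded in the same direction at both times. Of the genes higher at 2 days, 840 were also higher at 4 days, where 207 would be shared by independent lists of these sizes (one-sided Fisher's exact test, p below 1e-300, and below 2e-300 after adjustment over the 4 overlaps tested). Of those lower at 2 days, 732 were also lower at 4 days, against 160 for independent lists (p below 1e-300, adjusted p below 2e-300). The comparisons use different libraries throughout, but genes are not independent of each other. Both also rest on the same estimate of the spread of each gene, which makes the same genes easier to call at both times. The counts for independent lists, and the p-values against them, are therefore not the level expected without a shared response. Only 8 genes were higher at 2 and lower at 4 days, and 9 were lower and then higher, or 41 and 59 with the replicate block. The 840 genes higher at both times took 5.64 ± 0.803% of the reads in 2-day controls and 14.4 ± 0.749% after 2 days of contact. At 4 days their shares were 6.10 ± 0.482% and 15.5 ± 0.989% (SD, n = 3). Genes lower at both times took 1.78 ± 0.0532% and 0.704 ± 0.173% of the reads at 2 days. These shares come from the libraries by which the genes were chosen, so their direction is fixed by the choice and only their size is informative. Across the 13411 genes, the log2 contact effects at the 2 times had a Pearson correlation of 0.762 and a Spearman correlation of 0.651, across genes that are not independent replicates. With the replicate block the shared genes numbered 1489 higher and 1416 lower. Genes lower at both times numbered 407 without 2-day contact replicate 1, 396 without 2-day contact replicate 2 and 486 without 4-day contact replicate 2.

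In control mycelium, 754 genes were higher and 479 lower at 4 than at 2 days. Gene 249217 rose from 2.63 ± 1.496 to 869 ± 408 CPM (331-fold, log2 change 8.37 ± 1.21 SE, adjusted p = 0.00235). Gene 29538 rose from 0.0950 ± 0.0872 CPM, with 7 reads in the 3 libraries, to 11.3 ± 3.97 CPM (120-fold, log2 change 6.90 ± 0.76 SE, adjusted p = 0.000525). Its log2 change was 7.59 without 2-day replicate 1 and 6.24 without 2-day replicate 3. Gene 29538 was higher still with root contact, at 33.7 ± 22.7 CPM at 2 days and 258 ± 39.1 CPM at 4 days. Gene 71303 fell from 64.6 ± 28.7 to 4.47 ± 1.74 CPM (14.5-fold, adjusted p = 0.000442), and gene 423938 fell from 15.0 ± 7.73 to 1.26 ± 0.715 CPM (11.7-fold, adjusted p = 0.0053). With the replicate block the counts were 1729 higher and 1767 lower, and with DESeq2 they were 1170 and 1087. In a fit of the 6 control libraries alone they were 272 and 111. Leaving out 1 control library gave between 292 and 700 higher and between 68 and 553 lower, with the fewest without 4-day replicate 3.

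In mycelium on roots, 568 genes were higher and 436 lower at 4 than at 2 days. Gene 23495 was higher at 4 days, with 0.127 ± 0.0587 CPM at 2 days and 11.5 ± 15.2 CPM at 4 days (adjusted p = 0.00882), and 1 library carried most of that level (29.0 CPM in replicate 1 against 3.70 and 1.68 CPM). Its log2 change was 6.49 ± 1.24 SE, 4.398 without that library and 5.87 with the replicate block. Gene 410766 rose from 12.3 ± 14.0 to 782 ± 246 CPM (63.7-fold, log2 change 5.99 ± 0.98 SE, adjusted p = 0.00617), with 0 reads in the 2-day controls and 1 read in the 4-day controls. Its log2 change was 7.48 without 2-day replicate 2 and 6.82 with the replicate block. Gene 446852 fell from 1168 ± 580 to 92.3 ± 36.4 CPM (12.7-fold, adjusted p = 0.00152), and gene 188049 from 433 ± 195 to 33.5 ± 17.9 CPM (12.9-fold, adjusted p = 0.00535). Both also fell with time in controls, gene 446852 from 463 ± 196 to 90.4 ± 32.6 CPM (adjusted p = 0.016) and gene 188049 from 336 ± 247 to 68.2 ± 37.9 CPM (adjusted p = 0.0398). The replicate block gave 1067 higher and 1014 lower. DESeq2 gave 845 and 888, so the larger side depended on the method. With library size alone as scaling, 71.98% of the calls were higher, against 56.6% with TMM factors. Leaving out 1 contact library gave between 355 higher (without 4-day replicate 3) and 494, and between 179 lower (without 4-day replicate 2) and 379.

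Changes with time overlapped between the treatments, which share no library. Both tests rest on the same estimate of the spread of each gene, so independent lists are again not the level expected without a common change. In both, 192 genes rose, against 31.9 for independent lists (one-sided Fisher's exact test, p = 1.53e-102, adjusted p = 2.04e-102), and 87 fell, against 15.6 (p = 2.43e-41, adjusted p = 2.43e-41). Across genes, the time effects in control and contact mycelium had a Pearson correlation of 0.408 and a Spearman correlation of 0.374. With the replicate block, 459 genes rose and 362 fell in both treatments.

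Whether the contact effect itself differed between the days was tested as the interaction. For 137 genes the effect was more positive at 4 days, and for 69 it was more negative. Gene 415466 showed the largest difference with a more positive effect by the fixed rule. It stood at 0.507 ± 0.296 CPM in 2-day controls and 134 ± 63.1 CPM after 2 days of contact, and at 0.0489 ± 0.0848 CPM (6 reads) and 2492 ± 1506 CPM at 4 days (interaction log2 7.46 ± 1.18 SE, adjusted p = 0.0142). All 6 of these control reads were in replicate 3. Without that library the 4-day controls had 0 reads and the fitted interaction, which then depends on the prior count, was 11.78. It was 6.87 without 2-day control replicate 2, 6.74 without 4-day control replicate 2 and 6.86 without 4-day contact replicate 1. Gene 438832 had 2.96 ± 0.674 and 27.1 ± 20.3 CPM at 2 days and 1.96 ± 0.870 and 1388 ± 720 CPM at 4 days in controls and with contact (interaction log2 6.29 ± 0.93 SE, adjusted p = 0.0105, and 6.93 without 2-day contact replicate 2). In the other direction, gene 24837 had an interaction log2 of -3.52 ± 0.54 SE (adjusted p = 0.013), because its control level rose from 4.75 ± 1.22 to 89.5 ± 37.3 CPM while its contact level went from 9.56 ± 4.23 to 15.8 ± 2.29 CPM. Gene 440744 rose with time in both treatments, from 0.646 ± 0.377 to 69.5 ± 23.2 CPM in controls and from 12.1 ± 0.683 to 117 ± 10.9 CPM with contact (interaction log2 -3.45 ± 0.51 SE, adjusted p = 0.0105).

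Of the 137 genes with a more positive effect at 4 days, 135 were called higher at 4 days, 91 rose with time on roots and 55 fell with time in controls. Of the 69 with a more negative effect, 45 were called higher at 2 days and 42 rose with time in controls. The replicate block changed this balance. Of its 693 genes with a more positive effect, 610 were called higher at 4 days, 263 rose with time on roots and 464 fell with time in controls. Of its 505 with a more negative effect, 305 were called higher at 2 days and 271 rose with time in controls. These counts come from the same libraries as the interaction. Most genes called at one time only had no detectable difference between the days. Of 1051 genes higher at 4 days and not called at 2 days, 95 had a called interaction, and of 614 higher at 2 days and not called at 4 days, 29 did. With the replicate block, 429 of 1478 and 165 of 903 did. With the replicate block the interaction was called for 693 genes above and 505 below 0. Without the 4 replicate 1 libraries it was called for 826 and 584, and with any 1 library left out for between 41 and 261 above and between 16 and 119 below 0. With library size alone as scaling, 78.3% of the interaction calls were above 0, against 66.5% with TMM factors. DESeq2 called 418 above and 366 below 0, so that 53.3% were above 0 and most of that balance was gone.

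**Figure D3:**
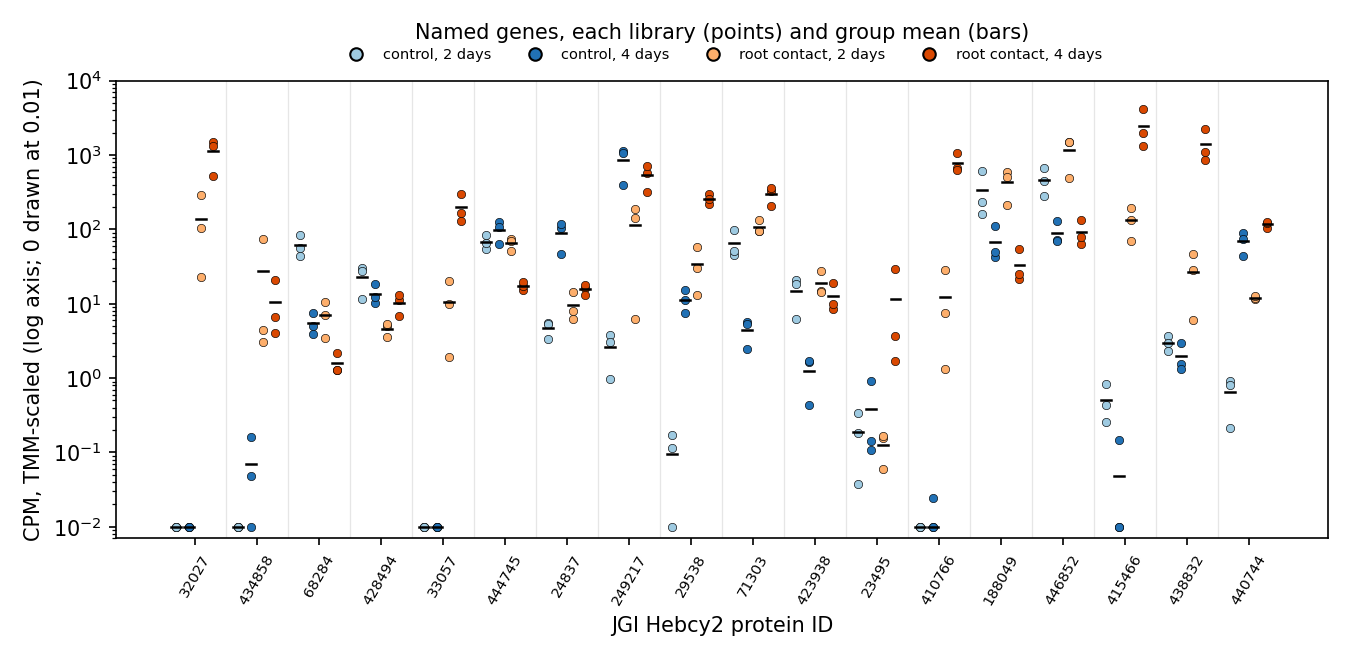
TMM-scaled CPM of the 18 named genes in each library (points) and as group means (bars), on a log axis with 0 drawn at 0.01. Genes 32027 and 33057 have no read in the control libraries, and gene 415466 reaches 2492 CPM after 4 days of root contact.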

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

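The tests on thinned libraries, on gene model length, on exchanged time courses and on shared reads were chosen after the data were seen, the last with its bounds written before its value was known. The other splits of the libraries were set before.

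The contact effect differed between the days by the interaction test for 137 genes with a more positive effect at 4 days and 69 with a more negative one. Among the named genes, the interaction log2 was 7.46 for gene 415466, 6.29 for gene 438832, 5.31 for gene 71303, -2.45 for gene 444745, -3.45 for gene 440744, -3.52 for gene 24837 and -6.12 for gene 249217. For gene 71303 the control level fell with time while the contact level rose from 108 ± 22.3 to 296 ± 78.4 CPM (SD, n = 3; adjusted p of the interaction 0.00167). For gene 249217 the interaction lay just inside the threshold (adjusted p = 0.0494), with 2.63 ± 1.496 and 113 ± 95.7 CPM at 2 days and 869 ± 408 and 539 ± 202 CPM at 4 days in control and contact libraries.

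When day labels were exchanged within each treatment, 1 of 100 draws, the real one, gave as many interaction calls as the real 206. The highest other draw gave 203. These draws do not decide whether chance can be excluded, although a share under 0.05 had been set as the bound, because exchanged days carry the changes with time themselves (1233 and 1004 calls). The 4 other draws above 100 calls all kept the day labels of one treatment in place, and the 79 draws that kept neither gave 0 calls, with the time effects left in the residual spread. Exchanging whole time courses (the 2- and 4-day libraries of one treatment and replicate number) between the treatments avoids this, but allows only 10 splits, too few for a share under 0.05. In a fit with a level for each time course, the real split gave 1895 calls, the 1 split of 10 with that many, and the highest other gave 0. In the other splits any real interaction enters the residual spread, so their 0 calls are not the level expected without an interaction.

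The 3898 genes called between contact and control at 4 days stand against a 2.44-fold difference in depth between the treatments. After thinning every library to equal depth, 78.7% of them were still called in the same direction, and their log2 changes moved by a median of 0.0569, which argues against depth alone as the cause. Without the trend on gene model length, 91.5% remained, which argues against that trend. Of the genes with under 90% unique reads, 14.18% were called higher, against 14.17% of the others (odds ratio 1.001, 95% interval 0.769 to 1.29, Fisher's exact test, two-sided p = 1), which argues against reads shared between near-identical models as the source of the increases. Contact with the root stays open as the biological explanation, and so does any step in collection or library making that differed between scraped and free-living mycelium, which the design does not separate from contact.

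For the comparisons of 3 against 3 libraries, 10 splits exist, too few for a share under 0.05. The real split gave 2536 calls for contact at 2 days, 3898 for contact at 4 days, 1233 for time in controls and 1004 for time on roots, and in each case it was the 1 split of 10 with that many, the highest other giving 0. That includes the 3 other splits in each comparison that part all 3 equally numbered pairs. These differ from the real one by exchanging the members of 1 pair. Every other split puts libraries of both real groups on each side, so any real difference enters the residual spread. Their 0 calls are therefore not the level expected without any effect.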

How the results depend on the processing

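Unique reads, thinning, removal of the length trend, leaving out replicate 1 and the overlaps with a library left out were chosen after the data were seen. Of 274 alternative counts, 155 stayed within 1.5 times the count reported, 48 rose beyond it and 71 fell below it. All 183 alternative values of the named genes (DESeq2, replicate block and each library left out) kept their direction and stayed past the threshold. The genes had been picked from the same libraries as the largest called changes without overlap, so this outcome is in large part fixed by the choice. Each gene was rerun only in a comparison that picked it. The interactions given above for genes picked only in other comparisons are therefore not among these values. Gene 410766 has no DESeq2 value for time on roots, because DESeq2 gave it no p-value. The interaction of gene 415466 went from 7.46 to 11.78 log2 without 4-day control replicate 3, which held all its reads in 4-day controls. The gene lists and their alternatives were not run, because no list could be matched to IDs, and the alternatives meant for normalized values were not run, because counts were used. In the simulation, where fewer genes were called than in the real data, a 2-fold change was recovered in 24% of genes. That share need not hold for the real comparisons. A gene not called is not shown to be unchanged.

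Fits without a filter, with a filter of 10 CPM in 3 libraries, with DESeq2 size factors in edgeR, with limma-voom, with unique reads, with thinned libraries or with the length trend removed (both without the block) left every count of calls within 1.5 times. Of these fits, only that of thinned libraries was used to recount the overlaps of the days, which also stayed within 1.5 times (723 and 499). The replicate block raised the counts to 2433 higher and 2132 lower for contact at 2 days, 3026 and 3003 at 4 days, 1729 and 1767 for time in controls, 1067 and 1014 for time on roots, and 693 and 505 for the interaction. The overlap of the days rose to 1489 and 1416. The block halved the common dispersion (0.0847 to 0.0401), ended 1 call at 4 days and changed no other call of those made without it. With thinning added, the blocked fit gave 1711 lower for contact at 2 days, 1395 and 1570 for time in controls, 929 and 875 for time on roots, and 592 and 381 for the interaction. With the length trend removed it gave 2697 and 2205 at 2 days, 3407 higher at 4 days, 1651 and 2276 for time in controls, 1110 and 1234 on roots, and 923 and 605 for the interaction. Leaving out the 4 replicate 1 libraries gave 3062 higher at 4 days, 1418 and 1773 for time in controls, 1209 and 1423 on roots, and 826 and 584 for the interaction. Of the calls made on all libraries, it kept 83.3% at 2 days and 93.5% at 4 days.

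Upper-quartile factors gave 1058 higher and 2179 lower at 2 days and 1256 and 3275 at 4 days. Library size alone gave 792 and 3424 at 2 days, 1071 and 3518 at 4 days, 255 lower for time on roots and 41 below 0 for the interaction. The contact counts follow the shift of the median gene (-0.44 and -0.40 log2 at 2 and 4 days under library size alone). For time on roots the median gene also shifted, to 0.163 log2 under library size alone against 0.0233 with TMM factors, in the direction of the counts. Whether that shift gave the counts on roots was not tested, and neither was the cause for the interaction. DESeq2 gave 1170 and 1087 for time in controls, 888 lower on roots, and 418 and 366 for the interaction. Only the 6 libraries compared gave 624 and 183 for contact at 2 days and 272 and 111 for time in controls. In the same kind of fit, contact at 4 days rose to 2636 and 2562 and time on roots to 598 and 529, both within 1.5 times. The gap in calls between the days of contact was thus wider than in the fit of all 12 libraries, which share an estimate of the spread. For DESeq2 and for these smaller fits the cause was not tested. Stricter definitions lowered counts by construction. A change of at least 2-fold left 610 lower at 2 days, 1199 and 1230 at 4 days, 264 lower for time in controls, 264 lower on roots, and overlaps of 540 and 393. Testing against 1.5-fold left 669 and 207, 871 and 679, 210 and 47, 275 and 127, and 54 and 16, in the order of the comparisons. The share of the first principal component fell to 47.6% with all tested genes.

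With each library left out in turn, no gene called changed sign. Counts ranged over 491 to 1197 lower at 2 days, 1191 to 1525 higher and 1063 to 1624 lower at 4 days, 292 to 700 and 68 to 553 for time in controls, 355 to 494 and 179 to 379 on roots, 41 to 261 and 16 to 119 for the interaction, and 396 to 850 for genes lower at both times. At 2 days, genes called lower fell to 588 without contact replicate 1 and 491 without contact replicate 2. At 4 days, counts fell to 1205 and 1241 without control replicate 3, 1191 and 1063 without contact replicate 1, and 1230 lower without contact replicate 2. For time in controls they fell to 386 and 233, and 359 and 314, without replicates 2 and 3 of 2 days, to 314 lower without replicate 1 of 4 days, and to 355 and 124, and 292 and 68, without replicates 2 and 3 of 4 days. On roots they fell to 359 and 277 without replicate 3 of 2 days, 364 and 250 and 355 and 180 without replicates 1 and 3 of 4 days, and 179 lower without replicate 2. Genes lower at both times numbered 407, 396 and 486 without 2-day contact replicates 1 and 2 and 4-day contact replicate 2. The count of interactions above 0 moved with every library, and that below 0 with every library except 4-day control replicate 1 (48). They rose to 224 and 108 without 2-day control replicate 1 and 261 and 119 without 2-day contact replicate 1, and fell to between 41 and 89 above 0 and between 16 and 48 below 0 without any of the others.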

Other observations

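All tests in this part were chosen after the patterns were seen. For the depth test on the replicate 1 libraries, the bounds were written before its value was known.

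A small set of genes was read almost exclusively in mycelium on roots. With every library thinned to 21.8 M reads, genes with at most 3 reads in the 3 controls and a mean of at least 10 CPM with contact numbered 7 at 2 days and 20 at 4 days, 6 of them at both. The reverse pattern, reads in controls and at most 3 with contact, was met by 0 genes at either time, and neither time comparison held such a gene. The 21 genes together had 49 reads in the 6 control libraries before thinning. They made up 0.0373 ± 0.0244% of the reads after 2 days of contact and 0.581 ± 0.221% after 4 days (SD, n = 3). Because 14 of them entered only by their level at 4 days, a higher level at 4 than at 2 days is in large part fixed by how they were chosen. Of the 7 chosen at 2 days, 6 had a higher mean at 4 days and 5 were called higher with time on roots, or 6 with the replicate block. Gene 32057, singled out after its values were seen, had the highest level, 2579 ± 1662 CPM after 4 days, with 4473, 1894 and 1369 CPM in the libraries. Only 83.7% of its reads were unique, so its level is uncertain where near-identical models share reads. Of the 16 genes with a control read, edgeR called the interaction for 0, without or with the replicate block. Without the block, 1 had an unadjusted p under 0.05. DESeq2 called the interaction for 3 of the 15 to which it gave an adjusted p. Most of the 16 had 0 reads in all controls of 1 day, so their fitted interaction depended on the prior count. For gene 410766, with 0 control reads at 2 days and 1 at 4 days, the log2 SE was 64. The lack of edgeR calls therefore does not show an equal contact effect on both days. For the 5 genes without any control read the interaction could not be estimated.

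As a set, these gene models were shorter than matched ones, and part of them lay close together in protein ID. Their median length was 333 nt, whereas 10000 random sets matched on abundance had a median of 1341 nt and none was below 732 nt (permutation test over the sets, one-sided p = 1e-04, the smallest they can give). For 13 of the 21, another of them lay within 100 in protein ID, against a median of 2 and at most 12 in matched sets (permutation test, one-sided p = 1e-04, again the smallest possible). The 3 genes without a unique read, named below, may hold reads of one another or of other models and were left out in turn. The 18 others had a median length of 411 nt against 1342 nt in matched sets (permutation test, one-sided p = 1e-04), and 9 of them had such a neighbour, against a median of 2 and at most 9 (permutation test, one-sided p = 5e-04). One hypothesis is that part of the set may belong to a few families or clusters of short gene models, but protein IDs are not map positions, and no coordinates or sequences were used here.

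Technical sources of this pattern were weighed. Reads from another source of one composition would keep the genes in 1 ratio between libraries. The 20 genes with at least 100 reads at 2 days instead had log2 ratios between the contact libraries with a mean SD of 1.34, above the median of 0.567 in random sets with as many reads (2e-04 of the sets were as large) and above 0.163 from counting alone. Reads spread over near-identical copies would give low unique shares, but the median unique share was 99.5%. For 5 of the 21 genes it was under 90%, and genes 32502, 32808 and 33164, singled out after their values were seen, had 0% unique reads and cannot be counted apart. A source whose composition varies between libraries stays open, as does a response of the fungus to the root, which is the difference the groups name.

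Replicate 1 stood apart in all 4 groups. Its deviations from the group means of log2 CPM had a mean correlation of 0.538 between the 4 groups (0.430 to 0.665 over the pairs of groups). After removal of the trend on gene model length the mean was 0.520, and in libraries thinned to equal depth it was 0.469, which argues against length and depth as the whole cause. A shared inoculum, day or library batch could give such a pattern, but the labels name none, and no biological explanation was tested.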
